A study of Mus musculus with 9 samples.

How the data were processed

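RNA sequencing of splenic CD4+ T cells from C57BL/6 mice was deposited as 1 table of transcripts per library. Per the labels' protocols, cells were kept with DMSO or 12.5 µM Compound 10 and then left unstimulated or given PMA and ionomycin, RNA was extracted with Qiagen kits, and libraries were made with Clontech SMART-seq. Per the submitters' processing notes, reads were trimmed with cutadapt and quantified with kallisto against mm10; versions and the annotation are not given in the sources used here. The estimated counts were deposited as kallisto assigned them to transcripts, without normalization between libraries, as deposited in each table. The TPM values (scaled by effective length to a fixed sum per library) were deposited in the same tables, per the file headers. The effective lengths of the same tables served as an offset in an alternative only.

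Each table held 109617 transcripts, of which 108214 matched GENCODE M21 (GRCm38) when the version of the identifier was ignored, and 63964 with the version. Unmatched transcripts held 0.542% to 0.829% of the counts. Estimated counts were summed over the transcripts of each of 45321 genes and rounded. Groups were taken from the sample titles, and all 9 libraries entered 1 model with a coefficient for each of the 4 groups. Coordinates are those of GENCODE M21.

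Genes were filtered with edgeR's filterByExpr by group, which left 14040, libraries were scaled by TMM, and contrasts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust shrinkage, glmQLFTest, 2-sided). Adjusted p-values are those of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. SE is the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 0.244, and the median SE was 0.299 for compound 10 in stimulated cells, 0.325 in unstimulated cells, 0.327 for stimulation in vehicle, 0.299 for stimulation under compound 10 and 0.441 for the interaction. Induced and repressed genes had an adjusted p under 0.05 and a change of at least 2-fold with stimulation in vehicle. A negative binomial simulation with no compound effect, run 40 times, gave the medians and covariance that the shared stimulated vehicle libraries produce by themselves. Its counts of genes passing are no such baseline, as the adjusted cutoff is stricter where few genes change.

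Gene lists were compared with the other genes by camera of limma 3.58.1 with a preset correlation of 0.01 between genes, for lists of at least 5 tested members, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The 32 lists, 29 of them large enough, were inducible cytokines, chemokines, textbook NFAT:AP-1 composite-element genes, inhibitory receptors, anergy, the NFAT family, the AP-1 family, immediate-early genes, NF-kB targets, activation surface molecules, resting and naive genes, T helper factors, STAT5 feedback, MYC with ribosome biogenesis, glycolysis, cholesterol synthesis, NRF2, heat shock, integrated stress, p53, aryl hydrocarbon receptor, interferon-stimulated genes, apoptosis, CD4 identity, regulatory T cells, mitochondrially encoded genes, and markers of CD8 T cells, B cells, monocytes, neutrophils, natural killer cells, and erythroid cells with platelets. These lists, the main tests and the comparisons were chosen before the data were examined. Gene groups and tests added after the data were seen are named below.

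Genes named in the text followed a rule. For compound 10 in each state and for stimulation in vehicle these were the 12 genes furthest up and the 12 furthest down with an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap between the libraries of the groups compared. Predicted genes, immunoglobulin and T cell receptor segments and pseudogenes were skipped. From each list at most 4 members with the smallest p were named, or any tested member of the cytokine, NFAT:AP-1, AP-1 and NFAT lists, and for the interaction the 10 genes with the smallest p. Others were chosen after their values were seen, namely the GTPase, SR and hnRNP genes beyond the rule.

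The test was checked on simulated counts for 14040 genes with 200 changed, in 10 simulations. With dispersions drawn gene by gene, 1.94% of 1.5-fold, 18.5% of 2-fold and 65.2% of 4-fold changes were recovered for compound 10 in stimulated cells, and 0.597%, 13.0% and 59.1% in unstimulated cells, with 10.3% and 10.1% of calls false. With dispersions on the trend with abundance, 28.2% and 19.3% of 2-fold changes were recovered, and false calls were 4.72% and 3.33%. A list of genes all raised 2-fold was called in 10 of 10 simulations for each. Counts were drawn independently for each gene, so this says nothing about lists whose genes are correlated. The data gave more calls than these simulations, which moves the adjusted cutoff, so the shares may differ there.

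Alternatives were median-of-ratios and upper-quartile scaling, no filter and a stricter filter (10 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), a transcript length offset, only the groups compared, a replicate block, no robust shrinkage, an adjusted p under 0.01, a 2-fold minimum, fry in place of camera, other selections of induced genes, and each library left out in turn. With 1 library left in a group, that library is assumed to vary like the other groups. Fry tests a list against no change, whereas camera tests it against the other genes, so they ask different questions. After the data were seen, ribosomal RNA genes left out, ribosomal RNA percent as a covariate, the pair of vehicle libraries richest in ribosomal RNA left out, and a GC trend removed per library were added, the counts of near-identical copies were summed, and the pair of stimulated vehicle libraries was split to select and to test induced genes. No outlier test was made, as no group holds 4 libraries. Some genes that the rule names are not reported here. Splicing and single transcripts were not analysed here.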

Results

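RNA sequencing measured the transcripts of splenic CD4+ T cells from C57BL/6 mice, a common inbred laboratory strain. The cells had been purified without antibody on the CD4+ cells themselves ("untouched") and kept for 1 h in vehicle (DMSO) or in 12.5 µM Compound 10. The series describes Compound 10 as a small molecule directed at NFAT:AP-1, a complex in which NFAT, activated by calcium, and AP-1, activated by MAP kinases, bind neighbouring DNA sites. Cells were then left alone or stimulated for 2 h with 10 nM PMA, which activates protein kinase C, and 1 µM ionomycin, which lets calcium into the cell. The 4 groups held 9 libraries: unstimulated vehicle (2), unstimulated compound 10 (2), stimulated vehicle (2) and stimulated compound 10 (3). Estimated counts per library were 10669821 and 16784788 in unstimulated vehicle, 13420384 and 13905405 in unstimulated compound 10, 21852830 and 19590608 in stimulated vehicle, and 14471624, 15693035 and 13886789 in stimulated compound 10. Levels are given as CPM, counts scaled to the size of the library (mean ± SD over the libraries of a group). Changes are given as log2 fold changes with their standard errors (SE).

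The libraries separated by stimulation on the first principal component (41.2% of the variance) and by compound on the next (22.3%). On component 3 (8.94%) library 1 lay below library 2 in each of the 4 groups, and the main model held no term for this number. Ribosomal RNA took 4.72% and 26.3% of the counts in the unstimulated vehicle libraries numbered 1 and 2, 3.58% and 13.8% in the stimulated vehicle libraries, 6.67% and 3.11% in unstimulated compound 10, and 9.66%, 1.78% and 7.48% in stimulated compound 10. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Of 45321 annotated genes, 14040 passed the filter on low counts and were tested.

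The response to PMA and ionomycin in vehicle gives the background against which the compound was set. Il2, the T cell growth factor gene, rose from 0.740 ± 0.231 to 1512 ± 131 CPM (n = 2 and 2), a log2 change of 10.97 (SE 0.42). The chemokine genes Ccl3 and Ccl4 rose by 9.53 (SE 0.45) and 9.09 (SE 0.51), the cytokine genes Tnf and Ifng by 6.95 (SE 0.57) and 5.97 (SE 0.57), the costimulatory ligand gene Cd40lg by 6.91 (SE 0.31), and Myc by 6.70 (SE 0.31). Il17a gave 2 counts over the unstimulated and 5345 over the stimulated vehicle libraries, a ratio of 2191 with an exact 95% counting interval of 606 to 18090. Il3 gave 0 counts before and 349 after stimulation, at least 95.4-fold higher against a floor of 3 counts over the group. Such intervals and floors cover counting error only.

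Other genes fell with stimulation. S1pr1, which encodes the receptor that guides lymphocytes out of lymphoid tissue, fell from 175 ± 50.4 to 12.3 ± 2.78 CPM (log2 change -3.82, SE 0.26). S1pr4 changed by -3.60 (SE 0.19), Txnip, an inhibitor of thioredoxin, by -3.56 (SE 0.35), Tsc22d3, the glucocorticoid-induced leucine zipper gene, by -3.28 (SE 0.21), and Il16 by -2.79 (SE 0.23). Among the fixed gene lists, 19 of 20 inducible cytokines, 11 of 12 textbook NFAT:AP-1 composite-element genes, 7 of 8 chemokines, 13 of 14 AP-1, ATF, MAF and BATF genes, and 17 of 20 genes each of the immediate-early, activation surface and MYC with ribosome biogenesis lists were higher. Adjusted over the list alone these counts were 19, 11, 7, 13, 18, 18 and 18. The NF-kB target list had 14 genes higher and 3 lower (adjusted over the list alone, also 14 and 3), and the resting and naive list 9 lower and 5 higher (11 and 6 adjusted over the list alone).

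In all, stimulation changed 3943 of 14040 genes in vehicle, 2012 higher and 1931 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), with 2695 of them at least 2-fold. On log2(TPM + 1), where the median of all genes lay at -0.17, the split was 924 higher and 1498 lower. The count was 2595 and 2425 without unstimulated vehicle library 1 or 2, and 1596 without the vehicle library richest in ribosomal RNA of each state. The set test called 20 of 29 lists, of which 13 also passed with an estimated correlation. The 7 that did not were T helper lineage factors (adjusted p = 0.0629 with an estimated correlation), glycolysis and hypoxia (0.0824), cholesterol synthesis (0.216), integrated stress (0.271), regulatory T cell markers (0.271), anergy (0.283) and NRF2 genes (0.417). The NRF2 call also ended without unstimulated vehicle library 2 (adjusted p = 0.0838) or stimulated vehicle library 1 (0.192).

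The design text names the comparison of compound 10 with vehicle, and in stimulated cells it asks which activation genes differ in the presence of the inhibitor. Several cytokine genes were lower. Il4 stood at 5.98 ± 1.52 CPM (n = 3) under compound 10 against 168 ± 14.0 CPM (n = 2) in vehicle, a log2 change of -4.81 (SE 0.26; adjusted p = 4.25e-06). Il5 changed by -4.30 (SE 0.77), Il13 by -3.57 (SE 0.38), Il17f by -3.13 (SE 0.23), Il21 by -2.28 (SE 0.30) and Il17a by -2.27 (SE 0.16). Il2 fell from 1512 ± 131 to 332 ± 94.4 CPM (-2.19, SE 0.24; adjusted p = 0.000107), and stayed far above its unstimulated 0.481 ± 0.0542 CPM. The other cytokine genes that fell were Lif (-2.07, SE 0.33), Il10 (-2.02, SE 0.38) and Csf2 (-1.35, SE 0.37), the last of which no longer passed without stimulated vehicle library 1 (adjusted p = 0.152) or 2 (0.0608).

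Not every cytokine gene was lower under the compound. Lta, which encodes lymphotoxin alpha, rose from 24.0 ± 7.01 to 57.1 ± 4.25 CPM (1.25, SE 0.21; adjusted p = 0.00122). Tnf was at 2088 ± 423 CPM with compound 10 and 1023 ± 488 CPM in vehicle (1.03, SE 0.41; adjusted p = 0.106), and Ifng at 908 ± 288 and 1320 ± 747 CPM (-0.54, SE 0.41; adjusted p = 0.408), neither past the threshold. Il3 (-1.10, SE 0.37; adjusted p = 0.0510) and Osm (1.10, SE 0.44; adjusted p = 0.0906) also missed it, as did Il6, Il9, Il22, Ltb and Tgfb1. Of 20 cytokine genes tested 10 were lower and 1 higher, or 11 and 3 adjusted over the list alone, with a list median of -1.34. The set test put the list below other genes (camera, adjusted p = 1.01e-09; adjusted p = 0.0533 with an estimated correlation).

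**Figure D1:**
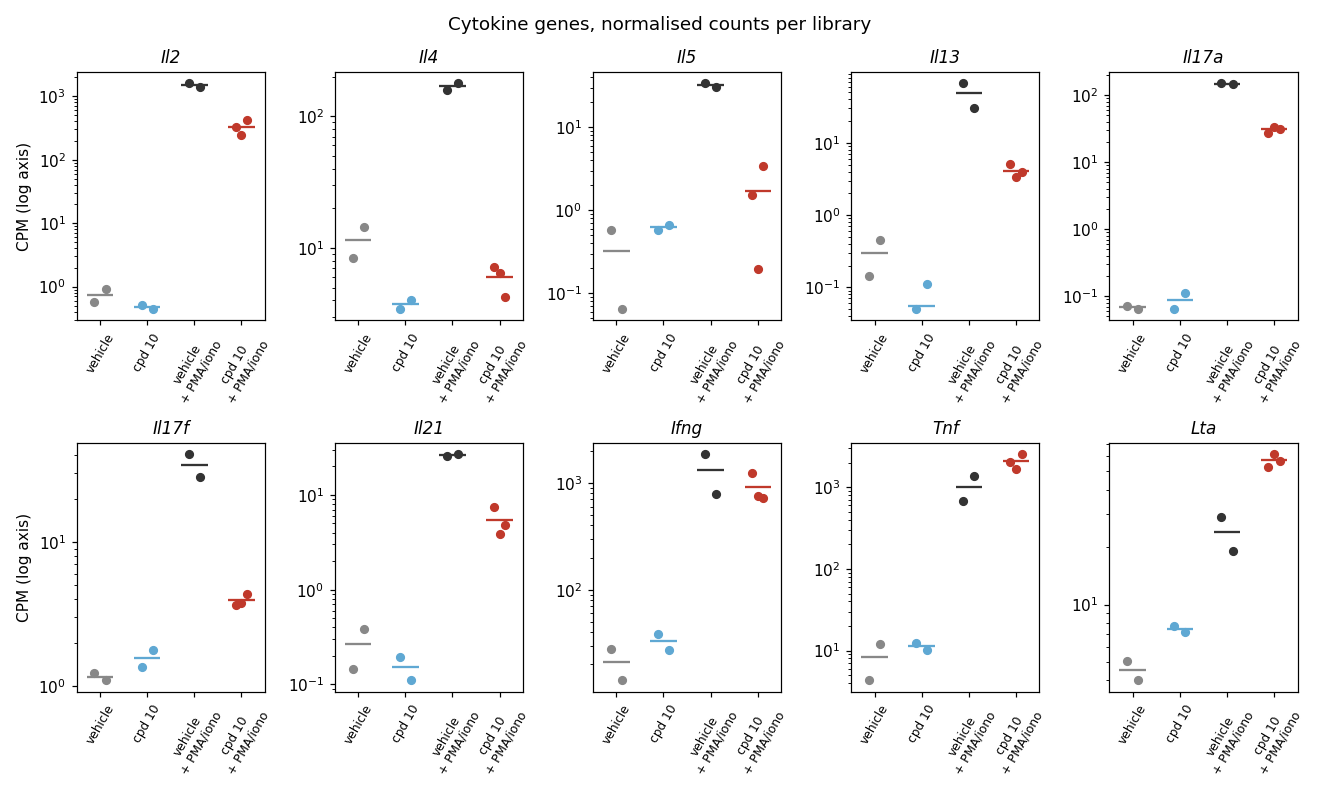
CPM of 10 cytokine genes in each of the 9 libraries (points) with the mean of each group (lines), on log axes whose range differs from panel to panel; the Il13 point of the unstimulated compound 10 library with 0 counts is drawn at 0.05 CPM. Under stimulation Il2, Il4, Il5, Il13, Il17a, Il17f and Il21 lie lower with compound 10 in all 3 libraries than in either vehicle library. Lta and Tnf lie higher in all 3, though Tnf did not pass the threshold, and the groups overlap for Ifng.

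The list of textbook NFAT:AP-1 composite-element genes, which shares 8 of its 12 members with the cytokine list, had 8 members lower and 0 higher (9 and 1 adjusted over the list alone), with a median of -1.41. Beyond the cytokines these were Il2ra, the high-affinity interleukin 2 receptor chain (-2.18, SE 0.21), Foxp3, the regulatory T cell factor (-1.47, SE 0.32), and Fasl, a death receptor ligand (-0.95, SE 0.23). Without stimulated vehicle library 2 the last pair missed the threshold (adjusted p = 0.0547 and 0.0830). Cd40lg stood at 2036 ± 345 against 2475 ± 9.55 CPM in vehicle (-0.28, SE 0.21; adjusted p = 0.394). The set test gave adjusted p = 3.86e-10 (camera), and adjusted p = 0.0533 with an estimated correlation.

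Of 20 activation surface and costimulatory genes 7 were lower and 1 higher (7 and 2 adjusted over the list alone). The 4 with the smallest p were Il2ra, Tnfsf14 (-2.15, SE 0.24), Crtam (-2.54, SE 0.31) and Tnfrsf9, which encodes 4-1BB (-1.20, SE 0.18). Of 8 chemokine genes 3 were lower (3 adjusted over the list alone): Xcl1 (-1.94, SE 0.26), Ccl1 (-4.19, SE 0.52) and Cxcl10 (-1.69, SE 0.28). Of 10 regulatory T cell markers 3 were lower (3 lower and 1 higher adjusted over the list alone), namely Foxp3, Il2ra and Ikzf2, which encodes Helios (-2.25, SE 0.18). These lists passed the set test at adjusted p = 0.00784, 0.0112 and 0.0443, and none did so with an estimated correlation (adjusted p = 0.596, 0.486 and 0.628 with an estimated correlation). Without stimulated vehicle library 1 they gave adjusted p = 0.0501, 0.112 and 0.0967, and the regulatory markers also missed the threshold without stimulated compound 10 library 2 (0.119) or 3 (0.0841), with a GC trend removed per library (0.0616) and with fry in place of camera (0.0543); Foxp3 itself gave 0.0547 without stimulated vehicle library 2. With the replicate block the chemokine and regulatory lists also missed the threshold (camera, adjusted p = 0.0537 and 0.113). Among inhibitory receptor and exhaustion-associated genes, which did not pass as a list (camera, adjusted p = 0.117), 4 of 13 were lower (4 adjusted over the list alone). Of these Cd160 fell from 45.4 ± 14.3 to 7.19 ± 1.26 CPM (-2.66, SE 0.24).

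Immediate-early and NF-kB target genes, which answer to kinase signals, moved both ways. Egr1, an early growth response factor, rose from 943 ± 17.0 to 4387 ± 539 CPM (2.22, SE 0.26), and Klf6 (1.86, SE 0.27), Btg2 (1.74, SE 0.19) and Zfp36, an mRNA decay factor (1.12, SE 0.20), rose as well. In that list 6 of 20 genes were higher and 2 lower (6 and 2 adjusted over the list alone; set test adjusted p = 0.0711). Among NF-kB targets 6 of 20 were higher and 3 lower (7 and 3 adjusted over the list alone; set test adjusted p = 0.145). Birc3 (1.45, SE 0.19), Icam1 (1.41, SE 0.20) and Tnip1 (1.32, SE 0.16) rose, and Nfkb1 fell (-1.44, SE 0.21). Few AP-1 family genes passed. Fos (0.29, SE 0.17), Fosl2 (0.10, SE 0.19) and Jun (0.28, SE 0.17) did not pass, while of 14 tested Maff (0.90, SE 0.19) and Junb (0.87, SE 0.28) were higher and Batf was lower (-0.77, SE 0.18), the same 2 and 1 adjusted over the list alone (set test adjusted p = 0.772). Without stimulated vehicle library 2 those calls gave adjusted p = 0.0606, 0.249 and 0.0600, and Junb was also lost without either unstimulated compound 10 library, stimulated vehicle library 1 or stimulated compound 10 library 2 or 3 (adjusted p from 0.0584 to 0.105). The NFAT family and calcineurin list had 4 of 13 higher and 2 lower (6 and 2 adjusted over the list alone; set test adjusted p = 0.136), among them Ppp3cc, a calcineurin catalytic subunit (1.90, SE 0.23), Rcan3, a calcineurin regulator (1.73, SE 0.21), and Nfat5 (-0.79, SE 0.16).

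Several genes of ribosome production were lower, and several of resting T cells higher. Of 20 MYC, ribosome biogenesis and polyamine genes 8 were lower and 0 higher (10 lower adjusted over the list alone; median -0.48), led by Polr1b, a subunit of RNA polymerase I (-2.05, SE 0.24), Pes1 (-1.44, SE 0.15), the fibrillarin gene Fbl (-1.23, SE 0.16) and Wdr43 (-1.16, SE 0.18). The set test gave adjusted p = 2.94e-06, and adjusted p = 0.0533 with an estimated correlation. Of 20 resting and naive T cell genes 7 were higher and 2 lower (7 and 3 adjusted over the list alone). Il7r, the interleukin 7 receptor gene, rose from 16.0 ± 0.817 to 145 ± 38.9 CPM (3.18, SE 0.28), S1pr1 from 12.3 ± 2.78 to 56.1 ± 6.16 CPM (2.18, SE 0.24), and Rasgrp2 by 2.05 (SE 0.17), while Slfn2 fell (-1.51, SE 0.19). The list passed at adjusted p = 0.0112, but gave adjusted p = 0.152 with an estimated correlation.

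Among genes with a mean log2 CPM of at least 4 whose libraries did not overlap between the groups, Arl5c rose furthest and Gbp2 fell furthest. Arl5c (chromosome 11, 97989578 to 97996181, GRCm38) rose from 13.6 ± 2.82 to 354 ± 53.4 CPM (4.70, SE 0.28), followed by Il7r and by Grap2, an adaptor of T cell receptor signalling (3.06, SE 0.23). Next came Nipal1 (2.81, SE 0.22), Grk6 (2.71, SE 0.20), Fam189b (2.56, SE 0.22), Spata13 (2.43, SE 0.20), Parp6 (2.43, SE 0.25), Rflnb (2.33, SE 0.23), Il16 (2.30, SE 0.22), Dgka (2.23, SE 0.23) and Egr1. Among the 12 of these genes that fell furthest, 6 encode interferon-inducible GTPases. Gbp2 fell from 395 ± 81.6 to 37.8 ± 18.5 CPM (-3.38, SE 0.36) and Ifi47 (chromosome 11, 49076587 to 49096974) from 1080 ± 130 to 134 ± 7.91 CPM (-3.01, SE 0.18), with Gbp4 (-2.78, SE 0.25), Igtp (-2.30, SE 0.25), and Tgtp1 and Tgtp2 (-3.18 and -2.77). Tgtp1 (chromosome 11, 48985327 to 48994172) and Tgtp2 (chromosome 11, 49057194 to 49064206) are near-identical copies between which reads may be split wrongly, so each value is uncertain. Their summed counts gave -3.004 (SE 0.24). The guanylate-binding (Gbp) genes also resemble each other. Srsf3, a splicing factor gene, fell from 547 ± 95.7 to 75.7 ± 16.6 CPM (-2.85, SE 0.23), Ubash3b by -2.41 (SE 0.20) and Penk by -2.27 (SE 0.28). The interferon regulatory factor gene Irf8 fell from 544 ± 50.7 to 114 ± 3.85 CPM (-2.25, SE 0.17), and Pfdn6 by -2.19 (SE 0.24), with Ikzf2 beside them. Over the genes of this paragraph the adjusted p ranged from 4.4e-06 to 0.000257.

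The remaining lists did not pass the set test in stimulated cells. The counts that follow give genes higher and lower, with those adjusted over the list alone in brackets. Among T helper lineage factors 2 and 3 of 17 passed (3 and 4), among STAT5 feedback genes 2 and 4 of 12 (3 and 4), among anergy-associated genes 2 and 1 of 13 (3 and 1), and among CD4 T cell identity genes 6 and 2 of 15 (7 and 2). Glycolysis and hypoxia genes gave 4 and 6 of 20 (5 and 6), cholesterol synthesis genes 2 and 3 of 19 (3 and 3), NRF2 genes 1 and 4 of 17 (1 and 4), heat shock genes 3 and 1 of 16 (3 and 1), integrated stress genes 4 and 4 of 19 (6 and 4), apoptosis regulators 4 and 2 of 17 (4 and 3), and mitochondrially encoded genes 0 and 1 of 13 (0 and 0). Of p53 target genes 5 of 19 were higher and 0 lower (6 and 0), led by Gadd45a (2.11, SE 0.18), Sesn1 (1.33, SE 0.18) and Bbc3 (1.22, SE 0.21). Of interferon-stimulated genes 5 of 19 were lower and 1 higher (5 and 1), with Gbp2 and Cxcl10 among the lower and Stat2 higher (1.89, SE 0.28). Of aryl hydrocarbon receptor targets, too few to test as a list, 1 of 4 was higher (1 and 1). The sign of the median, the mean and the test differed for the anergy, T helper, heat shock, p53, interferon, apoptosis, monocyte, erythroid and mitochondrial lists.

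No markers of other spleen cells passed, except those of natural killer cells. B cell markers (13 tested), monocyte, macrophage and dendritic cell markers (9), erythroid and platelet markers (8), neutrophil markers (4) and the single CD8 marker tested had 0 members changed in edgeR's test, also adjusted over the list alone, and 1, 2, 0, 1 and 0 at an unadjusted p under 0.05. Of 9 natural killer cell markers 4 were higher (4 higher and 1 lower adjusted over the list alone; set test adjusted p = 0.0567), all at low levels. Klrb1c rose from 0.284 ± 0.107 to 3.81 ± 0.501 CPM (3.72, SE 0.61), Gzma from 2.27 ± 0.103 to 6.48 ± 0.732 CPM (1.51, SE 0.29), and Prf1 and Klrd1 by 1.40 (SE 0.41) and 1.20 (SE 0.36). Prf1 gave adjusted p from 0.0940 to 0.143 without stimulated vehicle library 1 or 2 or compound 10 library 3, and Klrd1 from 0.0503 to 0.188 without stimulated vehicle library 1 or 2 or compound 10 library 1 or 3.

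**Figure D2:**
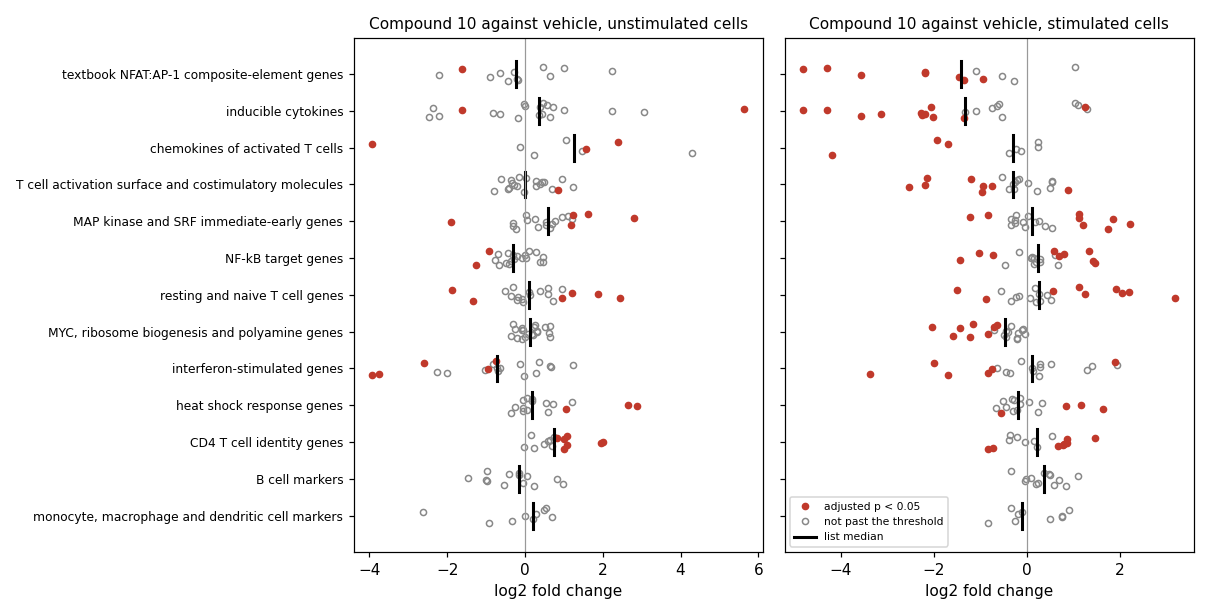
Log2 fold changes of the tested members of 13 gene lists (points) and list medians (bars), compound 10 against vehicle, in unstimulated (left) and stimulated cells (right); red points passed an adjusted p of 0.05. In stimulated cells the cytokine list has its median at -1.34 and the NFAT:AP-1 list at -1.41, while immediate-early genes lie on both sides of 0; Il6, the point farthest right on the left side, had 0 counts in vehicle, so its fitted value gives no bound.

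Across all genes, compound 10 changed 3234 of 14040 in stimulated cells, 1640 higher and 1594 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 1831 changed at least 2-fold. Without stimulated vehicle library 2 the count was 1973, and without the vehicle library richest in ribosomal RNA of each state, 1827. Of 29 lists 7 passed the set test, and 0 of the 7 with an estimated correlation, where camera gave 4 lists at an unadjusted p under 0.05.

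In unstimulated cells the comparison gives the effect of the compound by itself. Several genes of the interferon response were lower. Cxcl10 fell from 72.6 ± 23.1 to 4.80 ± 1.30 CPM (n = 2 and 2; -3.92, SE 0.36), and Gbp2 from 292 ± 78.7 to 21.5 ± 2.50 CPM (-3.76, SE 0.43). Tgtp1 (-3.74, SE 0.28; summed with its copy Tgtp2 -2.64, SE 0.27), Gbp7 (-2.69, SE 0.26), Ifi47 (-2.54, SE 0.21) and Gbp3 (-2.37, SE 0.24) fell likewise. The interferon-stimulated list had 5 of 19 genes lower and 0 higher (7 lower adjusted over the list alone), with a set test adjusted p = 2.77e-06, and adjusted p = 0.294 with an estimated correlation. Beyond this group Mpp7 (-2.52, SE 0.31), Cpne1 (-2.44, SE 0.31), Neurl3 (-2.38, SE 0.24), Srsf3 (-2.32, SE 0.26) and the adenosine kinase gene Adk (-2.26, SE 0.21) were lower too.

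Single genes of chaperones, of early signalling and of T cell identity were higher with the compound alone. Hspa1a, an inducible Hsp70 gene, rose from 16.0 ± 0.474 to 117 ± 43.8 CPM (2.88, SE 0.31) and its near-identical neighbour Hspa1b by 2.64 (SE 0.31). As the reads of this pair may be split wrongly both are uncertain, and summed they gave 2.83 (SE 0.29). Plaur, the urokinase receptor gene, rose from 2.93 ± 0.0359 to 20.4 ± 1.88 CPM (2.80, SE 0.32) and Zfp36 by 1.61 (SE 0.22). Cd5 and Cd6, which encode scavenger-type receptors of T cells, rose by 1.97 (SE 0.25) and 2.01 (SE 0.25), and Il7r by 2.44 (SE 0.28). The list also held Mgat1 (2.68, SE 0.23), Tsc22d1 (2.46, SE 0.26), Net1 (2.36, SE 0.19), Incenp (2.33, SE 0.23), Rgcc (2.21, SE 0.28), the selenoprotein P gene Selenop (2.21, SE 0.23), Hdac7 (2.09, SE 0.27) and Ube2m (2.10, SE 0.52; adjusted p = 0.0497), of which the last was lost without any of the 4 unstimulated libraries (adjusted p from 0.118 to 0.237) or either stimulated vehicle library (0.0840 and 0.0844).

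Among the lists, 7 of 15 CD4 T cell identity genes were higher (12 adjusted over the list alone; set test adjusted p = 1.08e-09, and adjusted p = 0.135 with an estimated correlation). Of 20 immediate-early genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.000567, and adjusted p = 0.294 with an estimated correlation). Of 16 heat shock genes 3 were higher (4 adjusted over the list alone; adjusted p = 0.00309, and adjusted p = 0.294 with an estimated correlation). Of 9 natural killer cell markers 1 was higher, Gzma (1.93, SE 0.33), or 4 adjusted over the list alone (adjusted p = 0.00246, and adjusted p = 0.294 with an estimated correlation). Of 19 integrated stress genes 4 were higher and 0 lower (6 and 2 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.489 with an estimated correlation), with the smallest p for Ddit3, which encodes CHOP (1.09, SE 0.21). Of 19 cholesterol synthesis genes 4 were higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0415, and adjusted p = 0.617 with an estimated correlation), with the smallest p for Sqle (0.95, SE 0.18). Calls rested on single libraries or on the test in several places. Fry, unlike camera, tests a list against no change and not against the other genes. Without unstimulated vehicle library 2 the stress and cholesterol lists gave adjusted p = 0.0723 and 0.121, and with fry in place of camera 0.0586 and 0.0976. The cholesterol list gave 0.133 without the vehicle library richest in ribosomal RNA of each state. Without compound 10 library 1 they gave 0.143 and 0.185 and the heat shock list 0.0507. Gzma gave 0.0610 and 0.0554 without the libraries numbered 2 of vehicle or compound 10. Ddit3 gave 0.0652 to 0.0952 and Sqle 0.0563 to 0.0952 without either vehicle library or compound 10 library 1.

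Of the cytokine genes Il4 and Il6 passed in unstimulated cells. Il4 fell from 11.4 ± 4.36 to 3.74 ± 0.424 CPM (-1.61, SE 0.30; adjusted p = 0.00864), and Il6, with 0 counts in vehicle and 13 under compound 10, was at least 3.81-fold higher (adjusted p = 0.0422), so that 1 of 20 genes was lower and 1 higher (2 and 1 adjusted over the list alone). Il4 missed the threshold without vehicle library 2 or either compound 10 library (adjusted p from 0.0536 to 0.0905), and Il6 without any of the 4 unstimulated libraries or stimulated compound 10 library 1 or 3 (0.0519 to 0.2). Il2 was at 0.740 ± 0.231 CPM in vehicle and 0.481 ± 0.0542 CPM with compound 10. The NFAT:AP-1 list had Il4 alone lower of 12 (1 adjusted over the list alone; set test adjusted p = 0.296). B cell and monocyte marker lists had 0 members changed of 13 and 9 in edgeR's test, also adjusted over the list alone, and 2 and 1 at an unadjusted p under 0.05.

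In all, compound 10 changed 1030 of 14040 genes in unstimulated cells, 623 higher and 407 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 676 of them at least 2-fold. This count was 263 or 269 without vehicle library 1 or 2 and 174 or 278 without compound 10 library 1 or 2; it was 294 without the vehicle library richest in ribosomal RNA of each state. The set test called 7 of 29 lists, and 0 of the 7 with an estimated correlation, where camera gave 4 lists at an unadjusted p under 0.05. The comparisons in unstimulated and stimulated cells share no library. Of the 623 genes higher in unstimulated cells 403 were also higher in stimulated cells, where independent lists would share 72.8, and of the 407 lower 260 were also lower, against 46.2. The opposite directions held 5 and 11 genes. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.405 and Spearman's rho = 0.488.

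Among the genes that stimulation raised, more were lower than higher under the compound. Of 1409 genes at least 2-fold higher with stimulation in vehicle, 418 (29.7%) were lower with compound 10 and 75 higher (median log2 change -0.37), and of 1286 genes at least 2-fold lower, 394 (30.6%) were higher and 49 lower (median 0.56). Of 10097 genes not called with stimulation, 887 (8.79%) were lower and 921 (9.12%) higher. The selection and the test share the stimulated vehicle libraries. In 40 simulations with no compound effect, 0 to 4 induced genes were lower and 0 to 2 repressed genes higher. Those counts are no baseline for 418 and 394, as only 0 to 5 genes passed for the compound in each simulation. That made the adjusted cutoff far stricter than in the data. The simulated medians of the compound effect, which need no such cutoff, were -0.07 for induced and 0.14 for repressed genes. Selected on the mean response of vehicle and compound 10 cells, 260 of 1320 induced genes were lower and 109 higher, and 212 of 1130 repressed genes higher and 91 lower. Selected on the response under compound 10, which favours genes it left high, 155 of 984 were lower and 169 higher, and 83 of 802 repressed genes were higher and 176 lower. Without stimulated vehicle library 2 the repressed count was 258. Across genes the covariance of the stimulation and compound effects was -0.383, against -0.164 from the shared libraries by simulation, a difference of -0.22 (Pearson's r -0.344, and -0.234 by simulation). With the induced genes selected by stimulated vehicle library 1 and compound 10 compared with library 2, 243 of 1325 were lower and 79 higher (median -0.21), and 206 of 944 repressed genes higher and 32 lower. The other way round 267 of 1217 were lower and 46 higher (median -0.35), and 235 of 1127 repressed genes higher and 41 lower. Part of the excess in gene counts may come from the shared libraries.

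Cells under compound 10 still responded to PMA and ionomycin. In them 3054 genes changed, 1541 higher and 1513 lower. In both vehicle and compound 10 cells 1126 genes were higher and 907 lower, where independent lists would share 221 and 208. The log2 responses correlated across genes (Pearson's r = 0.649, slope 0.554). Error in the vehicle response lowers such a slope by itself, so it does not measure how far the compound weakened the response. Of 20 cytokine genes 15 were higher with stimulation under the compound (17 adjusted over the list alone), as were 16 of 20 NF-kB target genes (18 adjusted over the list alone, with 1 lower) and 16 of 20 immediate-early genes, 1 being lower (17 and 1 adjusted over the list alone). On log2(TPM + 1), where the median of all genes lay at -0.21, the split was 557 higher and 1518 lower. The count was 1627 and 1506 without unstimulated compound 10 library 1 or 2. The set test called 17 of 29 lists, 11 of them also with an estimated correlation.

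The interaction tests whether the response itself differed between compound 10 and vehicle. Arl5c was nearly level with stimulation in vehicle (0.32, SE 0.26) and rose under compound 10 (3.68, SE 0.27), a difference of 3.36 (SE 0.36; adjusted p = 0.00249). Nipal1 (2.55, SE 0.31), Il16 (2.60, SE 0.30) and Tnfrsf26 (2.32, SE 0.26) also had the higher response under the compound. Il16 fell by 2.79 in vehicle and stood at -0.19 (SE 0.19) under compound 10. Tnfrsf26 was already lower in unstimulated compound 10 cells (25.2 ± 3.43 CPM) than in unstimulated vehicle (78.7 ± 2.58 CPM). With stimulation it stood at 46.0 ± 5.74 CPM under compound 10 and 28.8 ± 3.15 CPM in vehicle. The response was lower under the compound for Net1 (-2.40, SE 0.24), Arhgef3 (-2.82, SE 0.32), Ubash3b (-2.51, SE 0.31), the circadian gene Ciart (-2.20, SE 0.27) and Hnrnpu, a nuclear RNA-binding protein gene (-1.91, SE 0.24), with adjusted p from 0.00201 to 0.00314 over these 9 genes. Net1 was already high in unstimulated compound 10 cells (116 ± 18.8 CPM) and differed little between the stimulated groups (78.9 ± 0.455 CPM in vehicle and 76.4 ± 5.25 CPM with compound 10).

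Of the cytokine genes Il17f (-3.57, SE 0.40) and Il4 (-3.20, SE 0.39) had a lower response and 0 a higher one, by both adjustments (2 and 0 adjusted over the list alone), while Il2 did not pass (-1.56, SE 0.57; adjusted p = 0.228). The MYC, ribosome biogenesis and polyamine list had 4 genes with a lower response (12 adjusted over the list alone; median -0.83), among them Polr1b (-2.29, SE 0.36) and Pes1 (-1.37, SE 0.22), with adjusted p = 2.12e-11 and adjusted p = 0.0168 with an estimated correlation. It was the only list of the 15 called (of 29) to hold there. It was also the only 1 of them to pass with fry, which tests a list against no change and not against the other genes. In all 144 genes passed, 59 with the higher and 85 with the lower response under compound 10. With upper-quartile scaling, which moved the median of all genes from 0.01 to 0.11, the split was 81 and 66. This count depends on the model and on single libraries. It was 16 on log2(TPM + 1), 86 with limma-voom, 83 with a length offset, 430 with the ribosomal RNA covariate, 452 with DESeq2, and 239 or 512 under a stricter filter or none. With the replicate block, a term for the replicate number, it was 43. It was 43 or 52 without unstimulated vehicle library 1 or 2, 29 or 42 without unstimulated compound 10 library 1 or 2, 42 or 45 without stimulated vehicle library 1 or 2, and 264 or 48 without stimulated compound 10 library 2 or 3. Without the vehicle library richest in ribosomal RNA of each state 13 genes passed.

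**Figure D3:**
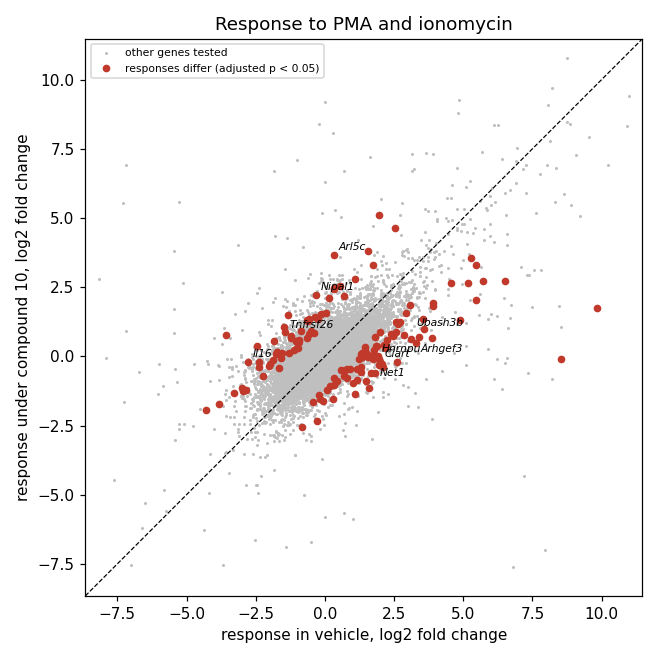
Log2 fold change with PMA and ionomycin in vehicle (horizontal) and under compound 10 (vertical) for 14040 genes; the dashed line marks equal responses. The 144 genes whose responses differed (red) lie on either side of the line, and 9 named genes are labelled.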

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

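Tests of the shared vehicle libraries and of a weaker stimulation were chosen only after the result was seen.

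The response to PMA and ionomycin differed between compound 10 and vehicle, by a test of the difference itself, for 144 genes. Among those with the smallest p were Net1 (-2.40), Arl5c (3.36), Arhgef3 (-2.82), Tnfrsf26 (2.32), Il16 (2.60), Ubash3b (-2.51), Nipal1 (2.55), Ciart (-2.20) and Hnrnpu (-1.91), on the log2 scale. Arhgef3 and Ubash3b rose with stimulation in vehicle by 3.30 and 3.12 and did not pass under the compound (0.49 and 0.61), while Arl5c and Nipal1 passed only under the compound (3.68 and 2.22). No single library left out ended any of these 9 calls, but 7 ended on log2(TPM + 1). Without both vehicle libraries richest in ribosomal RNA 5 ended (Arhgef3, Hnrnpu, Il16, Nipal1 and Tnfrsf26, adjusted p from 0.0537 to 0.0592), so that of the 9 only Net1 passed in both settings. The count of 144 ranged from 29 without unstimulated compound 10 library 1 to 264 without stimulated compound 10 library 2.

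Of the genes that stimulation raised, 418 were lower with compound 10. Both comparisons share the stimulated vehicle libraries. Chance values particular to 1 of these libraries would lower the induced genes only where the same library selects and tests them. With 1 of the pair selecting and the other compared with compound 10, the median of the induced genes was -0.21 (library 1 selecting) and -0.35 (library 2 selecting), against -0.37 with all libraries. This argues against chance values of single libraries as the whole cause, though not as a part of it. A deviation that both vehicle libraries share would pass the split. The labels do not say whether they came from separate animals or cultures. A weaker stimulation of every pathway alike would lower immediate-early and NF-kB genes about as much as cytokine genes if induced equally. For this test induced genes were selected on the mean response of vehicle and compound 10 cells. The 418 genes above were selected on vehicle alone. Instead of an equal fall, the median of 33 induced immediate-early and NF-kB genes was 0.15. It was 0.37 and -0.06 without stimulated vehicle library 1 or 2, and 0.07 without stimulated compound 10 library 2. The median of 19 induced cytokine genes was -1.35 (-2.17 without stimulated compound 10 library 1). The gap between these medians cannot settle the question, since genes were induced to different degrees. The compound alone also raised more immediate-early genes than it lowered in unstimulated cells. An action of the compound on part of the signalling, such as the NFAT:AP-1 complex named by the design, may explain this gap. That stays a hypothesis, since the complex itself was not measured.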

How the results depend on the processing

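The covariate, both settings without ribosomal RNA (genes or vehicle libraries) and the GC trend were chosen only after the data were seen. Named genes were mostly chosen for passing the threshold in these same data, so a direction kept in refits says little. Of 332 results for named genes 0 changed direction under any setting, and 120 missed the threshold in at least 1; of 66 list results 41 did so. In the order compound 10 in stimulated cells, in unstimulated cells, stimulation in vehicle, stimulation under compound 10, interaction, induced genes lower and repressed genes higher, the counts were 3234, 1030, 3943, 3054, 144, 418 and 394. Each library left out in turn gave 1973 to 3167, 174 to 1457, 2425 to 4347, 1506 to 3085, 29 to 264, 285 to 460, and 258 to 375. Settings not named below moved no count by over 1.5 times. On log2(TPM + 1) the counts were 975, 168, 2422, 2075, 16, 137 and 116, and at an adjusted p under 0.01 they were 1768, 256, 2274, 1626, 27, 253 and 215, as a stricter threshold must lower them. With a 2-fold minimum 1831, 676, 1786 and 237 remained for compound 10 in each state, stimulation under compound 10 and induced genes. Without both vehicle libraries richest in ribosomal RNA the counts were 1827, 294, 1596, 2877, 13, 259 and 153, with fewer samples. Without a filter compound 10 changed 1569 genes in unstimulated cells and the interaction 512. The interaction gave 239 genes under a stricter filter, 452 with DESeq2, 86 with limma-voom, 83 with a length offset and 430 with the ribosomal RNA covariate; the cause was not tested. Selected by the mean response, 260 induced genes were lower and 212 repressed genes higher; selected under compound 10, 155 and 83. With an estimated correlation 0 of the 7 list calls held in stimulated cells.

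The labels give the groups the same replicate numbers but state no shared origin. Deviations of same-numbered libraries correlated at 0.325 between the vehicle groups, 0.230 and 0.181 between the compound 10 groups, 0.180 and 0.0917 between the stimulated groups and -0.1002 between the unstimulated groups. Of the libraries numbered 1 or 2, 8 of 8 correlated best with their own number. These are not 8 independent results, as the deviations of the libraries in a group of 2 are exact opposites. With the replicate block the interaction gave 43 genes, 42 of them among the 144, and the other counts were 2681, 878, 3869, 2385, 350 and 347, with 5 list calls. With these depths and numbers of libraries, 2-fold changes were recovered in 18.5% (stimulated) and 13.0% (unstimulated) of simulated cases with dispersions drawn gene by gene. With dispersions on the trend with abundance the shares were 28.2% and 19.3%. Far fewer genes were changed in those simulations than the 3234 and 1030 called here, so the shares need not hold for these data.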

Other observations

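The gene groups described here, and the test on B cell and monocyte markers, were chosen only after the values were seen; the tests of ribosomal RNA, GC content, length and gene span were set before their results.

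Interferon-inducible GTPase genes were lower with compound 10 in both states. Of 17 tested, 13 were lower in unstimulated cells (median -2.15) and 15 in stimulated cells (median -2.21, or -1.40 without stimulated vehicle library 2). Besides Gbp2 and Ifi47, Iigp1 (-4.24, SE 0.53) and Gbp5 (-4.15, SE 0.35) fell furthest in unstimulated cells, where reads may be split wrongly among the similar Gbp genes. Fewer B cells or monocytes under the compound would lower their markers alike, but in unstimulated cells 22 such markers had a median of -0.103 (0.16 and -0.24 without unstimulated vehicle library 1 or 2, and -0.18 and 0.00 without unstimulated compound 10 library 1 or 2). Without the unstimulated vehicle library richest in ribosomal RNA the GTPase median there was -2.20. The fixed list of interferon-stimulated genes passed in unstimulated cells (adjusted p = 2.77e-06, and adjusted p = 0.294 with an estimated correlation) but not in stimulated cells (adjusted p = 0.230), where Stat2 was higher. In unstimulated cells Irf8 stood at 24.15 ± 2.127 CPM with compound 10 and 87.67 ± 10.84 CPM in vehicle. Lower interferon signalling may underlie the GTPase pattern in unstimulated cells. That stays a hypothesis, as the signalling was not measured and no test of it was made.

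Genes of SR splicing factors were lower as well, 8 of 13 in each state, with medians of -1.21 in stimulated and -0.89 in unstimulated cells. Srsf3 (-2.85), Tra2a (-2.14), Srsf6 (-2.13) and Srsf1 led in stimulated cells. With a GC trend removed per library the medians were -1.11 and -0.77, and with a transcript length offset -1.19 and -0.78, which argues against either trend as the whole cause. Of 20 hnRNP genes, 8 were lower and 1 higher in stimulated cells, led by Hnrnpa2b1 (-1.71, SE 0.21), and 2 lower in unstimulated cells. Whether splicing changed was not analysed here.

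If slowed elongation lost transcripts of long genes, genomic span would go with a lower fold change. Across 11382 protein-coding genes, which are not independent replicates, Spearman's rho was 0.0508 in stimulated and -0.0409 in unstimulated cells (1000 permutations, p = 0.001 for each, the smallest they can give). The sign in stimulated cells was opposite to the prediction, but permuting genes does not measure the spread between libraries. In unstimulated cells the weak trend went the predicted way, with median spans of 24305 bases for lower and 21793 for higher genes. Slowed elongation stays open in both states, as transcripts made before the compound was added were not told apart.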
